A study of Erysimum cheiri and Matthiola incana and Raphanus sativus with 44 samples.

How the data were processed

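Petals of half-open flowers from greenhouse plants of 10 Brassicaceae species were profiled by stranded poly(A) RNA-seq, in 22 forms with 2 libraries each, which the series describes as biological replicates. The values are FPKM as deposited, 1 value per library for 34133 Arabidopsis thaliana loci (34131 in the Brassica table). The submitters' processing notes name TopHat, DESeq, Cufflinks and Cuffdiff without versions, and the series states that expression was calculated with Arabidopsis as reference. The raw reads were not used here. Reads of all species were thus assigned to loci of another species, so a low value can reflect divergence from Arabidopsis as well as low transcript, and species were never fitted together. There were 3 entries that are not genes in the tables, and they stayed out of the tests.

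Groups are the form codes of the sample titles, because the colour and organism labels of some samples disagree with their titles. The colour labels of Erysimum give orange for B, pink for O and yellow for P and Y, those of Raphanus violet for DP and W and white-violet for LP. Those of Malcolmia give violet for LP and white-violet for P. The organism labels of Erysimum Y and Eruca Y are exchanged. The Erysimum columns headed PI were taken as the titles coded P, which is an inference. The 2 Aubrieta columns are identical and count as 1 library, so 43 libraries were counted. The 2 Matthiola W columns carry the same heading and are called libraries a and b here. No group was formed from the values.

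Counts were not used here, but low FPKM values of 7 species fall on steps. Over the libraries of these species, 12777 of 17365 loci seen in 3 or more libraries have a step, from which whole reads were recovered. Between 90.7% and 97.9% of the low values per species lay within 0.1 of a whole number of reads, against 20% if there were no steps. On simulated data 99.9% of stepped values and 22.6% of blurred values did so. Recovered reads per library ran from 163516 to 702045 in Erysimum, 45949 to 78587 in Iberis, 22221 to 28496 in Lobularia, 675125 to 1053794 in Malcolmia, 59438 to 229940 in Matthiola, 57161 to 114952 in Orychophragmus and 25027 to 96231 in Raphanus. Loci with a step held 6.78% to 39.1% of the FPKM of a library in Lobularia, 20.4% to 45.9% in Raphanus and 14.3% to 65.0% in the other 5 species, so these reads are a part of each library and its full depth stays unknown. A single read of a typical locus was worth from 0.375 FPKM in Malcolmia to 10.4 FPKM in Raphanus. Aubrieta, Brassica and Eruca show no steps, so their depth is unknown. Of 10 genes used in every cell, up to 3 were listed at 0 in a library, and 22 of 43 libraries listed at least 1 of them at 0.

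Within each of the 7 species with several forms, limma 3.58.1 (R 4.3.3) was fitted to log2(FPKM + 1) of genes with a mean of at least 1 FPKM in at least 1 form, with all forms of the species in 1 fit, empirical Bayes with an intensity trend, and Benjamini-Hochberg adjustment over all tested genes within a contrast. A gene is called at an adjusted p under 0.05. There were 15 contrasts. Adding 1 to FPKM pulls log2 differences of low genes towards 0. The 19 gene lists, with 188 loci, were fixed with the comparisons, and these choices were made before the data were examined. Lists with at least 3 tested members were tested with limma camera (preset correlation 0.01) and with fry as a self-contained test, adjusted over the lists of a contrast. Genes are named from these lists alone, since no annotation came with the series, and other loci are given by identifier. In every contrast the text names CHS, F3H, F3PRIMEH, FLS1, DFR, LDOX, TT19, UGT75C1, PAP1, PAP2 and TT8 where tested, in Erysimum, Brassica and Eruca also PSY, BCH1, BCH2, ZEP and CCD4, any other called member of the flavonoid, anthocyanin and carotenoid lists, and the called member with the largest change in each other list. Of the called genes without overlap between forms, the 5 highest and 5 lowest changes were also taken, and at most 2 up and 2 down are printed where no name is held. Levels between species are set side by side as FPKM, without a test. Percentiles of pigment genes in their libraries are given as a pooled median alone.

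The alternatives were a pseudocount of 0.1, no filter on low FPKM, quantile scaling, the replicate number as a block, no variance trend, only the 2 compared forms in the fit, each library left out in turn, Erysimum form Y left out, and camera with an estimated correlation. Chosen after seeing the data were limma voom on the recovered whole reads, Erysimum form P left out, and Erysimum list tests without P library 2. In tests on simulated counts with 200 changed loci per species, limma called the following shares of 16-fold changes: 0% in Lobularia, 24% in Orychophragmus and Raphanus, 72% in Iberis, 94% in Matthiola and Erysimum and 98% in Malcolmia, with at most 3 false calls per species. The voom fit called at least 92% of the same 16-fold changes, with 2 to 86 false calls. Of 4-fold changes, limma called 0% in Lobularia, 6% in Raphanus, 10% in Iberis, 18% in Orychophragmus, 30% in Erysimum, 54% in Matthiola and 82% in Malcolmia. A missing call therefore does not show that a gene was unchanged. The changed loci were drawn among loci with a step whose mean of recovered reads passed a floor. All forms shared the same mean profile. These shares thus do not cover genes with fewer reads, and neither shares nor false calls cover a shift of all genes. Steps, thinning and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.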

Results

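Petals of 10 Brassicaceae species were sequenced from half-open flowers in 22 colour forms with 2 libraries each, of which 43 are counted because the 2 Aubrieta columns are identical. In Raphanus sativus form W, the genes CHS, F3H, LDOX and TT19 were listed at 0 FPKM in both libraries, while form DP held 3036 ± 421 for CHS and 4984 ± 1431 for TT19. Both forms are labelled violet. RNA of other floral organs in W could not be told apart from a form difference, since the pollen gene VGD1 was higher in W. In Orychophragmus violaceus CHS, CHI, CHIL and F3H fell in form P against form W, and DXR, HDS and HDR of the plastid isoprenoid pathway rose. In Matthiola incana TT19 fell in the 3 coloured forms against form W, and CHS, F3H and LDOX separated form LP from DP and RB. The Orychophragmus calls were lost without P library 1, TT19 in Matthiola lost its call with quantile scaling, and CHS, F3H and LDOX lost theirs in both pairs without W library b. Erysimum cheiri form Y listed DFR, UGT75C1 and UGT79B1 at 0 in both libraries, of which UGT79B1 alone was called, a call lost with quantile scaling and under voom. Values are FPKM, written as mean ± SD over the 2 libraries of a form, or as both library values where 1 of them is 0 or where they lie far apart. Rose and fell mean an adjusted p under 0.05 in limma on log2(FPKM + 1) over all tested genes of the species. In every such gene named below the libraries of the compared forms did not overlap, except 4CL1 in Matthiola against W. This adds little, since many genes without a call did not overlap either. In contrasts of 2 against 2 libraries with calls, 24.2% (Raphanus LP against W) to 63.5% (Malcolmia) of all tested genes did not overlap. An entry of 0 is reported as listed at 0, since genes used in every cell were also listed at 0 in 22 of the 43 libraries.

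Raphanus form DP held transcripts of flavonoid and anthocyanin enzymes that were listed at 0 in form W. The colour labels are violet for DP and W and white-violet for LP. CHS, the first flavonoid enzyme, rose from 0 and 0 in the W libraries to 3036 ± 421 in DP (adjusted p = 0.00169). F3H rose to 853 ± 220.1, LDOX to 3131 ± 439, TT19 to 4984 ± 1431 and CHIL to 431 ± 149, each listed at 0 in both W libraries (adjusted p = 0.00443, 0.00169, 0.00169 and 0.00696). DFR rose from 14.0 and 0 to 2760.3 ± 461 and F3PRIMEH from 0 and 0 to 75.8 and 77.5 (adjusted p = 0.0313 and 0.0237). FLS1 rose from 14.4 ± 0.0621 to 149 ± 32.4 and UGT78D2 from 0 and 0 to 96.4 ± 11.1 (adjusted p = 0.0259 and 0.03). FLS1 in W lay near the 10.4 FPKM that a single read of a typical locus was worth there. Its small SD does not measure replicate spread. The decorating enzymes UGT79B1, UGT75C1, 3AT2 and SCPL10 were listed at 0 in both W libraries and rose to 58.1 ± 14.1, 24.1 ± 19.8, 33.2 ± 15.8 and 45.8 ± 17.3 (adjusted p = 0.0163, 0.0426, 0.0242 and 0.0175). Depth was not tested for the zeros of these enzymes. The locus AT4G22870 rose from 0 and 0 to 2107 and 1976 and AT1G48750 from 0 and 0 to 3142 and 1774 (adjusted p = 0.00169 and 0.0027). The files do not pair these identifiers with names.

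Of the regulators of the pathway in Raphanus, GL3 and 3 repressors rose in DP against W, and PAP1, PAP2 and TT8 were not called. The bHLH gene GL3 rose to 16.4 ± 0.694 in DP from 0 and 0 in W (adjusted p = 0.0259). PAP1 read 0 and 13.7 in DP and 0 and 0 in W, PAP2 0 and 18.7 and 0 and 0, and TT8 16.9 and 0 and 0 and 0, none of them called (adjusted p = 0.483, 0.535 and 0.483). Of the repressors, TRY, SPL9 and MYB4 rose from 0 and 0 to 13.4 ± 3.20, 19.2 ± 4.68 and 40.7 ± 32.2 (adjusted p = 0.03, 0.0257 and 0.0294). A single read of a typical locus was worth 10.4 FPKM in each W library. GL3, TRY and SPL9 in DP lay near that floor, so depth was not excluded for their zeros in W. Outside anthocyanin, the carotenoid desaturase ZDS rose from 189 ± 101 to 1450.3 ± 277 and the cleavage enzyme CCD1 from 34.8 ± 7.22 to 528 ± 85.6 (adjusted p = 0.0262 and 0.0126). CCOAOMT1 rose from 0 and 0 to 627 ± 102 and 4CL3 from 0 and 0 to 100.5 and 31.3 (adjusted p = 0.00545 and 0.0257). JAZ1 rose from 0 and 0 to 115 ± 27.8 (adjusted p = 0.0138).

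Organ markers also differed between Raphanus DP and W. The petal identity gene PI rose from 108 ± 25.2 in W to 826 ± 109 in DP, AP1 from 197 ± 10.3 to 688 ± 109, SEP1 from 33.7 ± 9.67 to 128 ± 2.67 and SEP3 from 2089 ± 68.6 to 4282 ± 30.2 (adjusted p = 0.018, 0.0216, 0.0492 and 0.022). The pollen gene VGD1 fell from 4170.2 ± 422 to 108 ± 41.9 and PPME1 from 224 ± 138 to 0 and 4.24 (adjusted p = 0.00696 and 0.0303). AG and SHP1 fell from 12.2 ± 0.0586 and 24.8 ± 11.8 in W to 0 in both DP libraries (adjusted p = 0.0416 and 0.0267). A single read of a typical locus was worth 10.4 FPKM in each W library. AG thus lay near that floor, where a small SD does not measure replicate spread. AVP1, a vacuolar proton pump, fell from 1431 ± 227 to 157 ± 55.9, and CYP83B1 from 126 and 647 to 3.81 ± 0.922 (adjusted p = 0.0163 and 0.0321). The photosynthetic genes RCA and LHCA2 rose from 436 ± 124 and 152 ± 13.2 to 2734 ± 328 and 731 and 761 (adjusted p = 0.0259 and 0.0175). The plastid loci ATCG00065 and ATCG00510 fell from 114000 and 8315 and from 57020 and 4157 to 0 in both DP libraries (adjusted p = 0.0137 and 0.016), and the files do not pair them with names.

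The gene lists summarise DP against W in Raphanus. Of 9 late anthocyanin genes 7 rose, 0 fell and 2 did not pass the test, against 8 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 1.39e-06; adjusted p = 0.354 with an estimated correlation; limma fry adjusted p = 0.00225). Of 10 early flavonoid genes 6 rose, 0 fell and 4 did not pass the test, against 6 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 9.09e-05; adjusted p = 0.354 with an estimated correlation). For 7 early phenylpropanoid genes 2 rose, 0 fell and 5 did not pass the test, against 4 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.00953; adjusted p = 0.395 with an estimated correlation). Of 7 petal identity genes 4 rose, 0 fell and 3 did not pass the test, against 5 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.00558; adjusted p = 0.392 with an estimated correlation). Of 4 carpel and ovule markers 0 rose, 2 fell and 2 did not pass the test, against 0 that rose and 2 that fell when adjusted over the list alone (limma camera, adjusted p = 0.00474; adjusted p = 0.354 with an estimated correlation). Of 4 pollen markers 0 rose, 2 fell and 2 did not pass the test, against 0 that rose and 2 that fell when adjusted over the list alone (limma camera, adjusted p = 0.00474; adjusted p = 0.354 with an estimated correlation). For 6 anthocyanin repressors 3 rose, 0 fell and 3 did not pass the test, against 3 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.183; adjusted p = 0.463 with an estimated correlation). Camera also called photosynthesis genes upwards (3 of 16 rose, 0 fell; adjusted p = 0.00445). The same held for sinapate and lignin genes (4 of 12 rose, 1 fell) and carotenoid biosynthesis genes (1 of 16 rose, 0 fell), each with adjusted p = 0.0488. With an estimated correlation these lists had adjusted p = 0.398. In all, 1232 of 11448 tested genes changed, 809 up and 423 down, and the median over all genes was 0.86 log2. Quantile scaling moved this median to 0.29 with 335 up and 305 down and voom on recovered reads to -0.54 with 608 up and 1116 down. W library 1 gave 69.2% of its FPKM to plastid loci. Leaving out single libraries gave from 1426 calls (without W library 2) to 2650 (without DP library 1), where the lone remaining library is assumed to vary like the other groups. Of the 35 called genes under the naming rule, 30 held with quantile scaling, all 20 with a read step held under voom and 24 held in every fit without 1 library.

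Raphanus form LP held CHS, TT19, LDOX, F3H and CHIL, which were listed at 0 in W. Against W, where both libraries read 0, CHS rose to 633 ± 85.7, TT19 to 1184 ± 288, LDOX to 274 ± 43.7, F3H to 102 ± 19.4 and CHIL to 83.8 ± 23.5 (adjusted p = 0.00498, 0.00498, 0.00744, 0.0267 and 0.0433). SCPL10 rose from 0 and 0 to 20.3 ± 2.58 and CCOAOMT1 from 0 and 0 to 207 ± 76.9 (adjusted p = 0.0482 and 0.0238). DFR was 62.7 and 12.5 in LP and 14.0 and 0 in W, and was not called (adjusted p = 0.594). Neither were F3PRIMEH at 37.0 and 8.87 against 0 and 0, FLS1 at 42.0 ± 13.6 against 14.4 ± 0.0621 and PAP2 at 15.4 and 0 against 0 and 0 (adjusted p = 0.0751, 0.252 and 0.646). UGT75C1, PAP1 and TT8 were listed at 0 in all 4 libraries. VGD1 fell from 4170.2 ± 422 to 729 ± 13.7 and SHP1 from 24.8 ± 11.8 to 0 and 0, while RBCS1B rose from 0 and 0 to 21.9 ± 2.77 and CAD5 to 94.5 ± 21.9 (adjusted p = 0.0482, 0.0495, 0.0482 and 0.0482). SCPL10 and RBCS1B in LP lay near the 10.4 FPKM of a single read of a typical locus in W. Depth was not tested for their zeros. AT4G22870 rose from 0 and 0 to 1180.0 and 1203, and AT1G07600 fell from 5080.0 and 6152 to 0 and 0 (adjusted p = 0.00267 and 0.0017). Of 10 early flavonoid genes 3 rose, 0 fell and 7 did not pass the test, against 7 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 7.24e-06; adjusted p = 0.476 with an estimated correlation). Of 9 late anthocyanin genes 3 rose, 0 fell and 6 did not pass the test, against 4 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.000112; adjusted p = 0.476 with an estimated correlation). Camera also called photosynthesis genes (1 of 16 rose, 0 fell) and sinapate and lignin genes (2 of 12 rose, 0 fell) upwards (adjusted p = 0.000264 and 0.0127). With an estimated correlation both had adjusted p = 0.476. By limma fry the adjusted p was 0.0882 for photosynthesis and 0.0201 for sinapate and lignin genes. It was 0.00896 for each of the early flavonoid and late anthocyanin lists. Of 11448 genes 293 changed, 174 up and 119 down. There were 21 up and 8 down with quantile scaling, and 234 up and 88 down with voom, which moved the median of all genes from 0 to 0.24. The fit of only the 2 compared forms left 0 calls, and the fit without the filter on low FPKM left 41. Leaving out DP library 1 left 0 calls with the lone DP library assumed to vary like the other groups, and leaving out LP library 1 gave 1141. Of the 18 called genes under the naming rule, 12 held with quantile scaling and 4 of 6 under voom.

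Raphanus form DP, labelled violet, held more CHS, F3H, LDOX and TT19 than form LP, labelled white-violet. CHS rose from 633 ± 85.7 in LP to 3036 ± 421 in DP and F3H from 102 ± 19.4 to 853 ± 220.1 (adjusted p = 0.0299 and 0.0328). LDOX rose from 274 ± 43.7 to 3131 ± 439 and TT19 from 1184 ± 288 to 4984 ± 1431 (adjusted p = 0.0205 and 0.0405). UGT75C1, 3AT2 and TRY rose from 0 and 0 to 24.1 ± 19.8, 33.2 ± 15.8 and 13.4 ± 3.20 (adjusted p = 0.0499, 0.0304 and 0.0377). A single read of a typical locus was worth 7.77 and 9.31 FPKM in the LP libraries, and depth was not tested for these zeros. DFR was 3086 and 2434 in DP against 62.7 and 12.5 in LP, yet its 2 LP libraries lay far apart and it was not called (adjusted p = 0.0769). FLS1 at 149 ± 32.4 against 42.0 ± 13.6 and F3PRIMEH at 75.8 and 77.5 against 37.0 and 8.87 were not called either (adjusted p = 0.0891 and 0.281). PAP1 read 0 and 13.7 against 0 and 0, PAP2 0 and 18.7 against 15.4 and 0 and TT8 16.9 and 0 against 0 and 0 (adjusted p = 0.485, 1 and 0.485). SEP3 rose from 1158 ± 173 to 4282 ± 30.2 and PI from 218 ± 55.8 to 826 ± 109 (adjusted p = 0.0165 and 0.0398). AP3 rose from 261 and 225 to 686 ± 188 and CCD1 from 134 ± 0.184 to 528 ± 85.6 (adjusted p = 0.0456 and 0.0389). JAZ1 rose from 0 and 0 to 115 ± 27.8 and 4CL3 from 0 and 0 to 100.5 and 31.3 (adjusted p = 0.02 and 0.0314). VGD1 fell from 729 ± 13.7 to 108 ± 41.9 and AVP1 from 852 ± 94.0 to 157 ± 55.9 (adjusted p = 0.0249 and 0.0294). RBCS2B fell from 1022 ± 44.5 to 248 ± 4.45 and AG from 19.1 ± 11.6 to 0 and 0 (adjusted p = 0.0314 and 0.0402). AT1G07600 rose from 0 and 0 to 2390.0 and 1955 and AT1G75750 from 0 and 0 to 393 and 255 (adjusted p = 0.00292 and 0.0176).

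For DP against LP in Raphanus the late anthocyanin list led. Of its 9 genes 4 rose, 0 fell and 5 did not pass the test, against 6 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.000687; adjusted p = 0.504 with an estimated correlation; limma fry adjusted p = 0.027). Of 10 early flavonoid genes 2 rose, 0 fell and 8 did not pass the test, against 4 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.0579; adjusted p = 0.606 with an estimated correlation). Of 7 petal identity genes 3 rose, 0 fell and 4 did not pass the test, against 5 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.00945; adjusted p = 0.504 with an estimated correlation). Of 4 pollen markers 0 rose, 1 fell and 3 did not pass the test, against 0 that rose and 2 that fell when adjusted over the list alone (limma camera, adjusted p = 0.0206; adjusted p = 0.504 with an estimated correlation). Of 11448 genes 916 changed, 564 up and 352 down. Quantile scaling gave 147 up and 224 down and voom 377 up and 1525 down, as the median of all genes moved from 0.72 to 0.17 and to -0.83. Leaving out single libraries gave from 1427 calls (without W library 2) to 2538 (without DP library 1, with the lone DP library assumed to vary like the other groups). Of the 27 called genes under the naming rule, 18 held with quantile scaling, 14 of 16 under voom and 17 in every fit without 1 library.

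**Figure D1:**
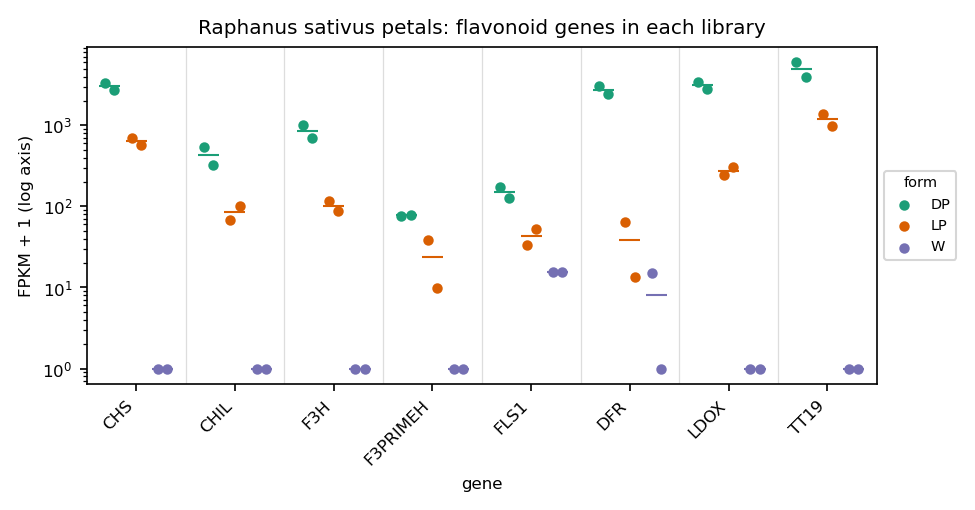
FPKM + 1 of 8 flavonoid genes in Raphanus sativus petals. Each point is 1 library, short lines are the means of the 2 libraries of forms DP, LP and W, and points at 1 are libraries listed at 0.

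Orychophragmus form P had less transcript than form W for 4 early flavonoid genes, although the label of P is violet and that of W white-violet. CHS fell from 1272 ± 7.38 in W to 280.4 ± 9.75 in P and CHIL from 184 ± 9.76 to 19.3 ± 8.14 (adjusted p = 0.024 and 0.0393). F3H fell from 562 and 533 to 70.9 ± 36.7 and CHI from 36.4 ± 12.5 to 0 and 0 (adjusted p = 0.0447 and 0.0393). TT19 fell from 2018 ± 109 to 214 ± 58.0 and 5MAT from 121 ± 9.90 to 0 and 0 (adjusted p = 0.0242 and 0.0242). PAL1 fell from 1119 ± 7.06 to 334 ± 39.3 (adjusted p = 0.0263). F3PRIMEH at 88.5 and 24.0 in P against 717 and 758 in W, DFR at 117 and 33.9 against 504 and 501, and FLS1 at 0 and 8.73 against 65.7 and 73.1 were not called (adjusted p = 0.0581, 0.0821 and 0.12). LDOX pointed the other way at 458 and 93.7 in P against 25.6 and 67.6 in W, as did PAP1 at 102 and 27.5 against 0 and 7.70, PAP2 at 48.0 ± 2.70 against 27.6 ± 9.32 and TT8 at 8.54 ± 3.58 against 8.20 and 0, none of them called (adjusted p = 0.254, 0.161, 0.353 and 0.545). UGT75C1 was 22.9 ± 5.91 and 33.2 ± 1.11 (adjusted p = 0.545). The locus AT4G22870 rose from 0 and 0 in W to 393 and 267 in P, AT1G15360 from 0 and 0 to 327 and 261, and AT3G15840 fell from 1708 and 1664 to 0 and 0 (adjusted p = 0.0224, 0.0224 and 0.0101). The files do not pair these identifiers with names.

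Plastid and organ genes of Orychophragmus changed as well. DXR, HDS and HDR, which feed the plastid isoprenoid pathway, rose in P to 1549.9 ± 215, 1791 ± 13.2 and 486 ± 39.7 from 314 ± 21.8, 665 ± 6.25 and 172 and 155 in W (adjusted p = 0.0242, 0.0243 and 0.0374). The chlorophyll b reductase NYC1 fell from 438 ± 19.6 to 25.5 ± 2.55, and the antenna gene LHCB1.1 rose from 6.24 ± 0.887 to 132 ± 68.9 (adjusted p = 0.024 and 0.0405). The partner petal identity genes split: AP3 rose from 719 ± 31.0 to 1849.6 ± 246, and PI fell from 4279.7 ± 128 to 1647 ± 398 (adjusted p = 0.0319 and 0.0432). CCOAOMT1 fell from 13254 ± 559.6 to 943 ± 331 while OMT1 rose from 483 ± 6.99 to 1649.5 ± 288, and HSP17.6II fell from 26.8 and 88.1 to 0 and 0 (adjusted p = 0.0242, 0.0272 and 0.0481). Of 11 early flavonoid genes 0 rose, 4 fell and 7 did not pass the test, against 0 that rose and 8 that fell when adjusted over the list alone (limma camera, adjusted p = 0.00117; adjusted p = 0.631 with an estimated correlation; limma fry adjusted p = 0.0355). Of 10 late anthocyanin genes 0 rose, 2 fell and 8 did not pass the test, against 0 that rose and 3 that fell when adjusted over the list alone (limma camera, adjusted p = 0.131; adjusted p = 0.631 with an estimated correlation). Of 9 plastid isoprenoid genes 3 rose, 0 fell and 6 did not pass the test, against 3 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.0535; adjusted p = 0.631 with an estimated correlation). Of 6 chlorophyll breakdown genes 0 rose, 1 fell and 5 did not pass the test, against 0 that rose and 1 that fell when adjusted over the list alone (limma camera, adjusted p = 0.206; adjusted p = 0.631 with an estimated correlation; limma fry adjusted p = 0.00222). Of 13226 genes 653 changed, 219 up and 434 down. There were 272 up and 318 down with quantile scaling and 973 up and 583 down with voom, and the median of all genes moved from -0.15 to -0.03 and to 0.34. Without the variance trend or without P library 1 there were 0 calls, and without W library 1 there were 2277, the lone library being assumed to vary like the other group. Of the 23 called genes under the naming rule, 20 held with quantile scaling, F3H and PI not among them, and 7 of 7 held under voom.

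Matthiola form W, labelled white, held more TT19 than any of the 3 coloured forms. TT19 was 8216 ± 35.9 in W and 2707 ± 50.7, 2780.2 ± 415 and 1995 ± 26.2 in DP, LP and RB, so it fell in the coloured forms together (adjusted p = 0.00105). The glycosyltransferases UGT78D2 and UGT79B1 fell from 1544 ± 120.5 and 281 ± 19.5 in W to 400.5 ± 12.6, 262 ± 63.8 and 556 ± 151, and to 121 ± 21.3, 129.8 ± 52.9 and 113 ± 7.18 (adjusted p = 0.00574 and 0.0407). The carotenoid hydroxylase BCH1 fell from 516 ± 25.9 to 160.4 ± 7.24, 170.3 ± 53.3 and 84.6 ± 24.0, whereas the cleavage gene CCD4 rose by 2.55 ± 0.39 log2 (with SE) to 59.5 ± 9.38, 145 ± 29.1 and 109.9 ± 27.6 (adjusted p = 0.00767 and 0.013). RCA fell from 1353 ± 166 to 454 ± 10.3, 484 ± 117 and 405 ± 0.467, PSBO1 from 426 ± 52.7 to 146 ± 46.9, 113 ± 14.2 and 102 ± 5.61, and LHCB2.1 and LHCA2 fell from 72.5 ± 14.2 and 320.4 ± 68.6 (adjusted p = 0.00574, 0.00813, 0.0291 and 0.041). SEP3 and AP1 fell from 898 ± 28.4 and 2201 ± 127, 4CL1 and 4CL3 from 128 and 103 and 3809.9 ± 202, and CCR1 from 438 ± 68.4 (adjusted p = 0.0118, 0.0242, 0.0351, 0.00617 and 0.00885). DXR and CCOAOMT1 rose from 90.2 ± 15.1 and 878 ± 195 (adjusted p = 0.0242 and 0.0163). AT2G46030 was listed at 0 in both W libraries and rose (adjusted p = 0.00499). AT1G78190 was listed at 0 in the 6 coloured libraries and fell from 99.4 and 66.7 (adjusted p = 0.00653).

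CHS, F3H, F3PRIMEH, DFR and LDOX were not called between Matthiola W and the coloured forms. CHS was 1539.7 ± 366 in W against 1911 ± 21.3, 347 ± 69.2 and 1757 ± 529 in DP, LP and RB, and DFR 47.7 ± 12.1 against 107 ± 15.7, 49.0 ± 0.702 and 84.1 ± 16.3 (adjusted p = 0.197 and 0.232). LDOX was 94.8 ± 29.4 against 305 ± 0.597, 51.3 ± 14.5 and 306 ± 28.8 and F3H 96.8 ± 68.3 against 261 ± 62.7, 15.7 ± 1.11 and 261 ± 87.6 (adjusted p = 0.108 and 0.744). F3PRIMEH was 287 ± 22.5 against 228 ± 21.8, 277 ± 49.0 and 139 ± 13.2 (adjusted p = 0.21). PAP1 was 62.9 ± 33.9 in W against 85.7 ± 30.4, 42.4 and 26.8 and 101 ± 5.78 and PAP2 17.9 ± 8.59 against 50.4 ± 22.9, 0 and 12.2 and 23.3 ± 17.5 (adjusted p = 0.794 and 0.904). UGT75C1 was 41.4 ± 14.4 against 10.8 ± 3.79, 0 and 9.88 and 15.8 ± 14.1 (adjusted p = 0.223). FLS1 was listed at 0 in 7 of 8 libraries and read 0 and 4.24 in LP, and TT8 was listed at 0 in 6 of 8 (adjusted p = 0.744 and 0.677). Of 15 photosynthesis genes 0 rose, 4 fell and 11 did not pass the test, against 0 that rose and 7 that fell when adjusted over the list alone (limma camera, adjusted p = 1.15e-06; adjusted p = 0.303 with an estimated correlation; limma fry adjusted p = 0.0179). Of 8 early phenylpropanoid genes 0 rose, 2 fell and 6 did not pass the test, against 0 that rose and 4 that fell when adjusted over the list alone (limma camera, adjusted p = 0.00233; adjusted p = 0.303 with an estimated correlation; adjusted p = 0.42 with quantile scaling). Of 8 late anthocyanin genes 0 rose, 2 fell and 6 did not pass the test, against 1 that rose and 3 that fell when adjusted over the list alone (limma camera, adjusted p = 0.34; adjusted p = 0.598 with an estimated correlation). Of 10 early flavonoid genes 0 rose, 1 fell and 9 did not pass the test, against 0 that rose and 2 that fell when adjusted over the list alone with a positive median and a negative mean (limma camera, adjusted p = 0.447; adjusted p = 0.729 with an estimated correlation). Of 13088 genes 771 changed, 310 up and 461 down. There were 398 up and 179 down with quantile scaling and 683 up and 406 down with voom, which moved the median of all genes from 0.12 to 0.53. Of the 20 called genes under the naming rule, 16 held with quantile scaling, where TT19 had adjusted p = 0.0562, and 9 held in every fit without 1 library. The locus AT3G08520 took 35.8% and 50.7% of the FPKM of the 2 W libraries. Without the variance trend there were 65 calls, and leaving out single libraries gave from 509 (RB library 1) to 1631 (DP library 1).

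Within the coloured Matthiola forms, LP was low in CHS, F3H, LDOX and 5MAT. CHS was 347 ± 69.2 in LP, 1757 ± 529 in RB and 1911 ± 21.3 in DP, so it rose in DP and fell in LP against RB (adjusted p = 0.019 and 0.0143). F3H was 15.7 ± 1.11, 261 ± 87.6 and 261 ± 62.7, LDOX 51.3 ± 14.5, 306 ± 28.8 and 305 ± 0.597, and 5MAT 22.5 and 4.15, 260.5 ± 33.2 and 275 ± 28.6 in that order. All 3 rose in DP against LP (adjusted p = 0.0394, 0.0338 and 0.0424) and fell in LP against RB (adjusted p = 0.0228, 0.0195 and 0.0243). CAD5 and CCOAOMT1 ran the other way, at 598 ± 19.1 and 3324 ± 599 in LP, 130.1 ± 19.7 and 1370.5 ± 119 in RB, and 121 ± 21.3 and 1170.5 ± 128 in DP. Both fell in DP against LP (adjusted p = 0.019 and 0.0414) and rose in LP against RB (adjusted p = 0.0142 and 0.042). CCD1 was 215 ± 40.7 in DP and fell against 639 ± 3.93 in LP and 619.5 ± 14.9 in RB (adjusted p = 0.0353 and 0.0277). In LP against RB, AVP1 fell from 2463 ± 677 to 870.5 ± 45.5, 4CL3 fell from 3384 ± 231 to 1659 ± 91.7, and 4CL1 rose from 14.8 ± 7.88 to 102 ± 22.5 (adjusted p = 0.0246, 0.0142 and 0.0477). DP held less 4CL3 than RB, 1722 ± 28.5 (adjusted p = 0.0224).

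No gene of the early flavonoid and late anthocyanin lists was called between Matthiola DP and RB. CHS, F3H and LDOX had no call there (adjusted p = 0.861, 1 and 1). For DP against LP, TT19, DFR, F3PRIMEH, PAP1 and PAP2 had adjusted p = 1, 0.343, 0.754, 0.504 and 0.356, and for LP against RB 0.188, 0.479, 0.149, 0.27 and 0.501. For DP against RB, TT19 had adjusted p = 0.154, F3PRIMEH 0.227, DFR 0.661, PAP1 0.884 and PAP2 0.657. FLS1, UGT75C1 and TT8 were not called in DP against LP (adjusted p = 0.746, 0.746 and 0.773), in DP against RB (adjusted p = 1 for each) or in LP against RB (adjusted p = 0.67, 0.664 and 0.682). AT4G11650 rose from 0 and 0 in LP and in RB to 179 and 166 in DP, and AT2G20340 fell from 757 and 385 in LP and 704 and 522 in RB to 24.1 and 4.86 (adjusted p = 0.0275, 0.0224, 0.0261 and 0.0224). For DP against LP, of 8 late anthocyanin genes 2 rose, 0 fell and 6 did not pass the test, against 3 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.00259; adjusted p = 0.164 with an estimated correlation). Of 11 sinapate and lignin genes 0 rose, 2 fell and 9 did not pass the test, against 0 that rose and 4 that fell when adjusted over the list alone (limma camera, adjusted p = 0.000254; adjusted p = 0.164 with an estimated correlation). Camera also called early flavonoid and glucosinolate genes upwards (adjusted p = 0.0149 and 0.0452) and early phenylpropanoid and petal identity genes downwards (adjusted p = 0.0357 for each). With an estimated correlation each of these had adjusted p = 0.193. Of these, the early flavonoid call alone held with quantile scaling. By limma fry all lists called by camera in DP against LP had adjusted p from 0.0509 to 0.389. The fry adjusted p was 0.0956 for early flavonoid genes in LP against RB and 0.268 for early phenylpropanoid genes in DP against RB. For LP against RB, of 10 early flavonoid genes 0 rose, 2 fell and 8 did not pass the test, against 1 that rose and 4 that fell when adjusted over the list alone (limma camera, adjusted p = 0.0179; adjusted p = 0.308 with an estimated correlation). For DP against RB, of 8 early phenylpropanoid genes 0 rose, 1 fell and 7 did not pass the test, against 0 that rose and 2 that fell when adjusted over the list alone (limma camera, adjusted p = 0.0122; adjusted p = 0.672 with an estimated correlation; adjusted p = 0.0578 with quantile scaling). DP against LP had 30 changed genes (18 up, 12 down; 128 up and 46 down with voom), DP against RB 110 (91 up, 19 down) and LP against RB 95 (67 up, 28 down; 27 up and 36 down with voom). Without W library b these counts became 0, 1 and 2. Without DP library 1 they became 817, 884 and 185, and without LP library 1 they became 507, 0 and 559, the lone library being assumed to vary like the other groups. Of 16, 12 and 17 called genes under the naming rule in DP against LP, DP against RB and LP against RB, 4, 10 and 16 held with a pseudocount of 0.1, 12, 11 and 13 with quantile scaling and 0, 0 and 2 in every fit without 1 library. CHS kept its call in DP against LP with that pseudocount, and F3H, LDOX and 5MAT lost it (adjusted p from 0.0732 to 0.121).

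**Figure D2:**
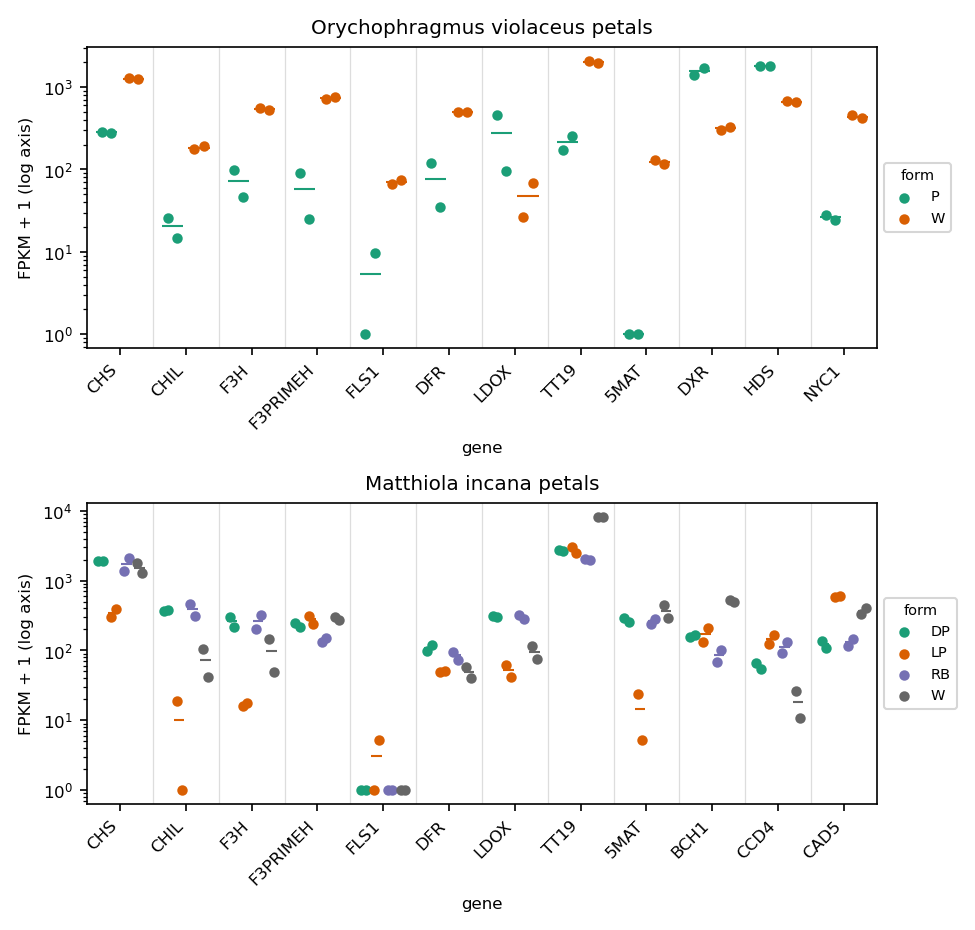
FPKM + 1 of 12 pigment and phenolic genes in petals of Orychophragmus violaceus (forms P and W) and Matthiola incana (forms DP, LP, RB and W). Each point is 1 library, short lines are form means, and points at 1 are libraries listed at 0.

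Malcolmia maritima form P showed more transcript than form LP for 6 photosynthesis genes and for CHIL, a flavonoid helper protein. CHIL rose from 88.5 ± 35.9 in LP to 442 ± 40.8 in P (adjusted p = 0.046). RCA rose from 1670.4 ± 36.3 to 4983 ± 662 and PSBO1 from 1332 ± 16.1 to 3249.7 ± 242 (adjusted p = 0.0468 and 0.0487). LHCB1.3 rose from 128 ± 4.60 to 459 ± 126 and LHCA1 from 75.7 ± 15.3 to 194 ± 9.26 (adjusted p = 0.0468 and 0.0489). CCD4 rose from 56.0 ± 14.6 to 165 ± 8.07 and BCH1 from 230.0 ± 30.9 to 575 ± 92.5 (adjusted p = 0.0487 and 0.0489). NCED3 rose from 3.72 ± 0.592 to 34.9 ± 3.04 (adjusted p = 0.046). CHS reached 6688 ± 697 in P and 1929 ± 979 in LP without being called (adjusted p = 0.0587). F3H was 89.3 ± 2.03 against 7.58 and 58.1 and TT19 545 ± 15.2 against 44.6 and 250.5 (adjusted p = 0.182 and 0.112). F3PRIMEH was 306 ± 31.1 against 25.3 and 291 and UGT75C1 315 ± 18.7 against 167 ± 72.0 (adjusted p = 0.295 and 0.121). DFR was 106 ± 0.0417 against 32.8 and 104 and LDOX 132 ± 14.9 against 97.2 ± 37.3 (adjusted p = 0.326 and 0.334). FLS1 was 65.9 ± 15.9 against 47.2 ± 10.2 (adjusted p = 0.317). PAP1 was 23.5 ± 3.70 against 18.0 ± 1.18 and PAP2 30.8 ± 4.24 against 29.0 ± 3.11 (adjusted p = 0.398 and 0.841). TT8 was 0.912 ± 0.0840 against 0.357 and 2.67 (adjusted p = 0.816). AT4G39366 rose from 0 and 0 to 445 and 1141 and AT4G39364 fell from 416 and 557 to 0 and 0 (adjusted p = 0.0204 and 0.00373), and the files give no names for them.

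The list view of Malcolmia followed the photosynthesis genes. Of 16 photosynthesis genes 6 rose, 0 fell and 10 did not pass the test, against 12 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 1.7e-05; adjusted p = 0.677 with an estimated correlation; limma fry adjusted p = 0.159). Of 10 early flavonoid genes 1 rose, 0 fell and 9 did not pass the test, against 4 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.115; adjusted p = 0.677 with an estimated correlation). Of 16 carotenoid biosynthesis genes 1 rose, 0 fell and 15 did not pass the test, against 2 that rose and 5 that fell when adjusted over the list alone (limma camera, adjusted p = 0.115; adjusted p = 0.677 with an estimated correlation). Of 4 carotenoid cleavage genes 2 rose, 0 fell and 2 did not pass the test, against 2 that rose and 1 that fell when adjusted over the list alone (limma camera, adjusted p = 0.522; adjusted p = 0.677 with an estimated correlation). Of 12871 genes 526 changed, 356 up and 170 down, and voom called 403 up and 1085 down with the median of all genes moved from -0.03 to -0.37. Quantile scaling and a pseudocount of 0.1 each left 2 calls, AT4G39366 and AT4G39364, and the fit without the variance trend left 1. Leaving out LP library 1 or either P library gave 0 calls against 999 without LP library 2, the lone library being assumed to vary like the other form.

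No gene was called between Iberis amara forms PI and P. F3PRIMEH was 151 ± 25.6 in PI and 19.5 ± 10.7 in P, FLS1 521 ± 91.2 and 148 ± 23.6, and TT19 2966 ± 1082 and 1195 ± 349 (each with adjusted p = 0.76). CHS was 660.3 ± 149 and 379.7 ± 12.8, F3H 569.8 ± 66.1 and 332 ± 109, DFR 147 ± 65.6 and 25.4 and 217, and UGT75C1 75.3 ± 23.0 and 35.6 ± 21.8. LDOX was 21.1 and 6.27 in PI and 0 and 49.4 in P (adjusted p = 0.911), and PAP1 and PAP2 were each listed at 0 in 3 of 4 libraries. Of 9 early flavonoid genes 0 rose, 0 fell and 9 did not pass the test, against 2 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.0363; adjusted p = 0.805 with an estimated correlation; limma fry adjusted p = 0.771). In limma 0 of 10555 genes were called, 580 had unadjusted p under 0.05, and voom on recovered reads called 60. Libraries of the 2 forms did not overlap for 25.1% of genes, against 33.3% by chance for values without ties. Ties at 0 lower the chance share, so these shares cannot be compared. Without PI library 2 there were 1489 calls, while leaving out either P library gave 0, the lone library being assumed to vary like the other form.

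No gene was called between Lobularia maritima forms P and W, at 22221 to 28496 reads recovered per library from loci with a step. LDOX was 44.1 ± 6.75 in P and 15.6 ± 9.65 in W, TT19 182 ± 94.7 and 70.3 ± 45.2, and FLS1 5.24 and 0 and 40.9 and 121 (each with adjusted p = 0.71). CHS was 47.6 ± 23.4 and 7.16 and 54.7, F3H 40.8 and 9.87 and 36.9 ± 12.7, DFR 42.5 ± 2.53 and 11.9 and 45.8, and UGT75C1 4.03 ± 0.0939 and 0 and 4.07, with the same adjusted p. A single read of a typical locus was worth 3.82 and 3.69 FPKM in the P libraries. UGT75C1 thus lay near that floor, where a small SD does not measure replicate spread. Of 4 late anthocyanin genes 0 rose, 0 fell and 4 did not pass the test, against 0 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.0624; adjusted p = 0.91 with an estimated correlation). Of 6 heat shock genes 0 rose, 0 fell and 6 did not pass the test, against 0 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.0624; adjusted p = 0.91 with an estimated correlation). W library 2 stood apart for this list, as HSP70 was 6.76 and 534 in W libraries 1 and 2 against 11.5 and 5.55 in P, and HSP101 was 1.59 and 306 against 0 and 0. The summed heat shock FPKM was 8.35 and 2840 in W and 11.5 and 5.55 in P. In limma 0 of 8801 genes were called, 374 had unadjusted p under 0.05, and voom called 22. Libraries of the forms did not overlap for 19.6% of genes, against 33.3% by chance for values without ties. Ties at 0 lower the chance share, so these shares cannot be compared. Leaving out W library 1 gave 1732 calls while leaving out either P library gave 0, the lone library being assumed to vary like the other form.

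Erysimum form Y had low values for late anthocyanin genes. The xylosyltransferase UGT79B1 was listed at 0 in both Y libraries and fell against 39.0 ± 1.60 in B, 83.9 ± 55.5 in O and 20.3 ± 0.249 in P (adjusted p = 0.0462). LDOX was 0.903 ± 0.0676 in Y against 67.7 ± 6.83 in B, 216 and 60.3 in O and 39.5 and 158 in P, and TT19 0 and 3.07 against 70.1 ± 6.61, 1108 and 112 and 229.5 ± 21.5 (adjusted p = 0.111 and 0.194). A single read of a typical locus was worth 0.638 and 0.580 FPKM in the Y libraries. LDOX in Y lay near that floor, where a small SD does not measure replicate spread. DFR was listed at 0 in both Y libraries and was 14.8 ± 1.97 in B, 81.3 and 19.1 in O and 5.49 and 263 in P, and UGT75C1 was 0 and 0 against 9.82 ± 6.35, 55.5 ± 30.8 and 19.0 and 2.99 (adjusted p = 0.711 and 0.514). CHS, F3H and F3PRIMEH also had their lowest means of the 4 forms in Y, at 148 ± 56.3, 24.4 ± 13.8 and 7.62 ± 5.62, beside 546 ± 26.0, 92.3 ± 3.54 and 42.4 ± 5.43 in B, with none called (adjusted p = 0.767, 0.682 and 0.752). FLS1 was 11.4 ± 2.62 in Y (adjusted p = 0.961). PSY was highest in Y at 628 ± 89.4, beside 263 ± 13.6 in B and 269 and 477 in O, with BCH2 at 109 ± 18.3 in Y (adjusted p = 0.961 and 0.961). ZEP was 425 ± 68.8 in Y and BCH1 79.6 ± 3.36, and CCD4 was not called (adjusted p = 0.979, 0.961 and 0.663). PAP1 was 2.81 and 0 in Y, and PAP2 and TT8 were listed at 0 in both Y libraries (adjusted p = 0.773, 0.961 and 0.961). Of 9 late anthocyanin genes 0 rose, 1 fell and 8 did not pass the test, against 0 that rose and 5 that fell when adjusted over the list alone (limma camera, adjusted p = 1.01e-12; adjusted p = 0.144 with an estimated correlation; limma fry adjusted p = 0.0221). Camera in Y also called sinapate and lignin, anthocyanin activator, heat shock and vacuolar genes downwards (adjusted p = 0.000157, 0.0161, 0.0162 and 0.0162). The same held for early flavonoid, early phenylpropanoid and glucosinolate genes (adjusted p = 0.0211, 0.0282 and 0.0282). With an estimated correlation these lists had adjusted p from 0.145 to 0.483. By limma fry their adjusted p ran from 0.0759 to 0.579. AT5G04790 rose from 0 in the 6 other libraries to 123 and 160.2 (adjusted p = 0.00994), and 4 of 14788 genes changed in Y, 2 up and 2 down. The UGT79B1 call was lost with quantile scaling (adjusted p = 0.0560), under voom (adjusted p = 0.136), with a replicate block (adjusted p = 0.0985) and in 7 of the 8 fits without 1 library (adjusted p from 0.106 to 0.848).

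Erysimum form P had the highest mean of CCD4, the carotenoid cleavage gene, without a call. CCD4 was 49.1 ± 7.35 in P against 1.58 ± 0.674 in B, 2.25 ± 1.84 in O and 0.530 and 0 in Y (adjusted p = 0.135). P library 2 had Spearman correlations of at most 0.694 with the other 7 Erysimum libraries and of 0.775 with Orychophragmus W library 2, while P library 1 reached 0.868 to 0.891 with 6 Erysimum libraries. Whether P library 2 is a second replicate of Erysimum P is therefore in doubt for every value of form P. The 2 P libraries disagreed for PSY at 238 and 2.84, ZEP at 427 and 25.8, BCH1 at 76.7 and 12.9 and BCH2 at 72.2 and 4.61 (adjusted p = 0.367, 0.367, 0.385 and 0.367). They also differed for DFR, for LDOX and for PAP2 at 0 and 173 (adjusted p = 0.38, 0.367 and 0.443). TT19 and PAP1 at 17.9 and 18.4 lay closer together, and UGT75C1 was not called (adjusted p = 0.367, 0.367 and 0.91). CHS in P was 295 and 575, F3H 33.9 and 116, F3PRIMEH 18.8 and 175, FLS1 11.3 and 0 and TT8 0 and 7.95 (adjusted p = 0.778, 0.634, 0.56, 0.367 and 0.526). Of 4 carotenoid cleavage genes 0 rose, 0 fell and 4 did not pass the test, against 2 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.081; adjusted p = 0.512 with an estimated correlation; limma fry adjusted p = 0.00526). Of 16 carotenoid biosynthesis genes 0 rose, 0 fell and 16 did not pass the test, against 0 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.00133; adjusted p = 0.512 with an estimated correlation). Of 8 anthocyanin activators 0 rose, 0 fell and 8 did not pass the test, against 0 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.013; adjusted p = 0.512 with an estimated correlation). Camera also called the late anthocyanin list upwards, with 0 of its 9 genes called (adjusted p = 0.0212; adjusted p = 0.512 with an estimated correlation). For the carotenoid biosynthesis, activator and late anthocyanin lists in P, limma fry gave adjusted p = 0.335 each. Without P library 2, chosen after seeing the data, the camera calls of the carotenoid biosynthesis, activator and late anthocyanin lists were all lost. The activators turned their direction, with a lone P library left in that fit. AT3G03820 fell to 0 and 0 in P (adjusted p = 0.0244), and 2 genes changed, both down. With the replicate number as a block 0 calls were left in P. With form P left out, chosen after seeing the data, the counts of changed genes were 7 in B, 2 in O and 15 in Y.

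**Figure D3:**
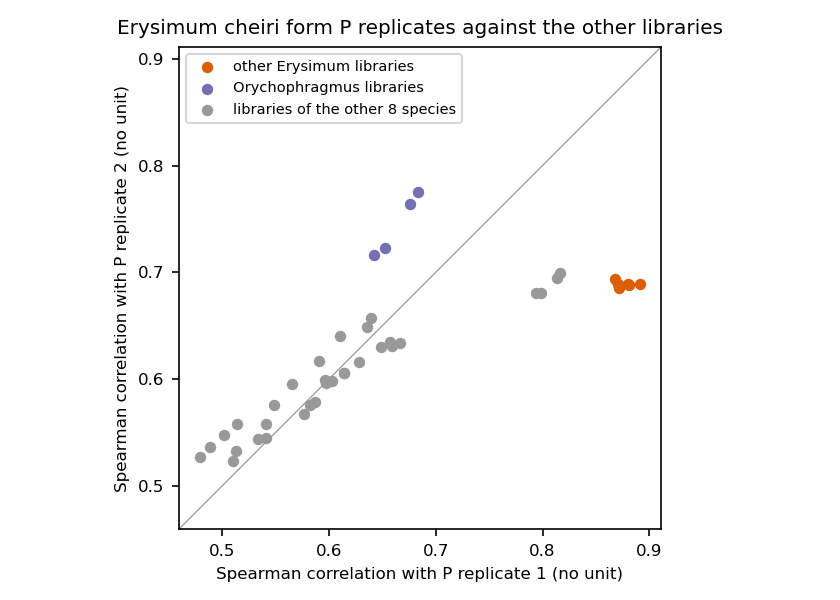
Spearman correlation over loci of each library outside form P with Erysimum cheiri P replicate 1 (horizontal) and P replicate 2 (vertical). The grey line marks equal correlation.

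Erysimum form O had the highest means of CHS, F3H, F3PRIMEH and FLS1 among the 4 forms, none of them called. CHS was 3556 and 886 in O and 546 ± 26.0 in B, F3H 329.6 ± 6.62 and 92.3 ± 3.54, and UGT75C1 55.5 ± 30.8 and 9.82 ± 6.35 (each with adjusted p = 0.997). FLS1 was 31.9 ± 18.6 in O and 5.07 ± 0.678 in B, F3PRIMEH 104 ± 49.0 and 42.4 ± 5.43, PAP1 34.8 and 7.77 and 4.19 ± 1.78, PAP2 4.80 ± 2.80 and 2.31 ± 1.39, and TT8 5.98 and 0 and 0 and 0, with the same adjusted p in O. DFR, LDOX, TT19, PSY, BCH1, BCH2, ZEP and CCD4 shared this adjusted p in O, and in B the genes always named had adjusted p from 0.895 to 0.961. BCH1 was 126 ± 19.8 in O and 35.7 ± 3.80 in B, BCH2 61.0 ± 3.88 and 63.0 ± 5.94, and ZEP was highest in B at 895 ± 48.6 beside 460.2 ± 108 in O (adjusted p = 0.895 in B). Of 11 early flavonoid genes 0 rose, 0 fell and 11 did not pass the test, against 3 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 1.92e-09; adjusted p = 0.0824 with an estimated correlation). Of 9 late anthocyanin genes 0 rose, 0 fell and 9 did not pass the test, against 4 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 6.49e-06; adjusted p = 0.19 with an estimated correlation). Camera in O also called photosynthesis, early phenylpropanoid, carotenoid biosynthesis and sinapate and lignin genes upwards (adjusted p = 2.39e-05, 0.000194, 0.00488 and 0.00831). With an estimated correlation these had adjusted p from 0.184 to 0.52, and none of their genes was called. By limma fry the adjusted p in O was 0.0678 for early flavonoid and 0.161 for late anthocyanin genes. It ran from 0.139 to 0.614 for the other lists called by camera in O. The summed photosynthesis FPKM was 2202 and 14201 in O libraries 1 and 2 against 6490 and 6434 in B. The O libraries thus lay far apart, with library 1 below both B libraries. In B, of 7 heat shock genes 0 rose, 0 fell and 7 did not pass the test, against 0 that rose and 0 that fell when adjusted over the list alone (limma camera, adjusted p = 0.0008; adjusted p = 0.942 with an estimated correlation). Camera in B also called plastid isoprenoid genes downwards (adjusted p = 0.0104; adjusted p = 0.942 with an estimated correlation). For the heat shock and plastid isoprenoid lists in B, limma fry gave adjusted p = 0.861 each. The summed heat shock FPKM was 14039 and 14270 in B, and 10729, 4503 and 4188 in library 2 of O, Y and P against 99.1, 76.2 and 315 in library 1. AT3G28530 rose in B from 0 in the 6 other libraries to 66900 and 54710, and AT2G40205 rose in O from 0 to 1189 and 1515 (adjusted p = 1.51e-05 and 0.00111). Of 14788 genes 1 changed in B, up, and 2 in O, 1 up and 1 down. The means set against O, B and Y include P library 2, whose place in the species is in doubt. Without P library 1 the counts for B, O, P and Y became 2165, 1683, 5898 and 1819, the lone P library being assumed to vary like the other groups. Without O library 1 they became 2, 1, 0 and 0.

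**Figure D4:**
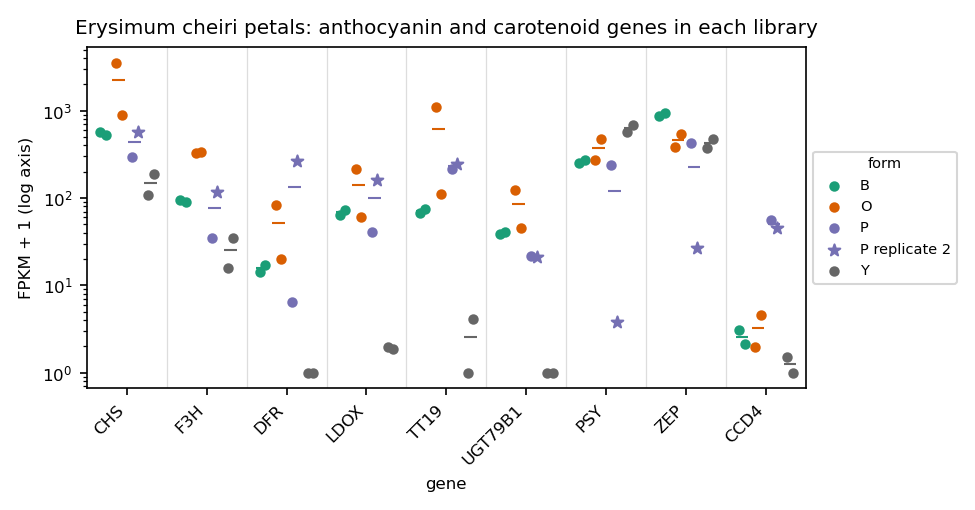
FPKM + 1 of 9 anthocyanin and carotenoid genes in Erysimum cheiri petals, forms B, O, P and Y. Each point is 1 library, stars mark P replicate 2, short lines are form means, and points at 1 are libraries listed at 0.

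The species with 1 form each add levels without a test. Aubrieta cultorum, whose 2 columns are identical and count as 1 library, held CHS at 2514, F3H 1914, F3PRIMEH 478, DFR 1099, LDOX 665, TT19 16546 and UGT75C1 213. In Aubrieta 7 of 13 early flavonoid genes and 7 of 10 late anthocyanin genes were above 0, with FLS1, 3AT2, SCPL10 and BGLU10 among those listed at 0. It held PAP1 27.6, PAP2 197 and TT8 5.08. Brassica oleracea petals listed F3H, F3PRIMEH, DFR, LDOX, TT19, UGT75C1 and TT8 at 0 in both libraries, with CHS at 20.2 and 66.1, FLS1 at 16.2 and 23.0, PAP1 at 0 and 59.6 and PAP2 at 16.1 and 29.6. Their carotenoid genes read 43.5 and 44.9 for PSY, 48.8 and 55.1 for BCH1, 96.0 and 76.1 for BCH2, 14.9 and 19.4 for ZEP and 0 and 4.96 for CCD4. Eruca sativa petals read 467 and 361 for PSY, 355 and 255 for BCH1, 29.9 and 13.8 for BCH2, 217 and 95.0 for ZEP and 0 and 0 for CCD4. Eruca held CHS at 30.0 and 33.8, DFR at 28.0 and 6.18, LDOX at 55.1 and 38.8, TT19 at 30.3 and 145 and F3H at 0 and 9.39. It held F3PRIMEH at 0 and 4.85, UGT75C1 at 0 and 2.35 and PAP2 at 0 and 25.2, with FLS1, PAP1 and TT8 listed at 0 in both libraries. CHS was above 0 in 21 of the 22 forms, Raphanus W being the exception. Tables of different species were normalised apart, so these levels are set side by side and not tested.

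PSY, the entry to carotenoids, and CCD4, which cleaves them, were set side by side across species after their values were seen. PSY was above 100 FPKM in Eruca Y and Erysimum B, O, P and Y by mean, and in all of these but Erysimum P the mean of CCD4 was at most 2.25. Iberis, with the most CCD4 at 1567 ± 775 in P and 1109.7 ± 90.7 in PI, listed PSY at 0 in all 4 libraries, and Aubrieta held CCD4 at 413 beside PSY at 3.26. Raphanus W and Brassica Y were low in CCD4 without high PSY, at 4.34 beside 5.33 and 2.48 beside 44.2. This comparison between species was not tested, and a low value can reflect divergence from Arabidopsis as well as low transcript.

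**Figure D5:**
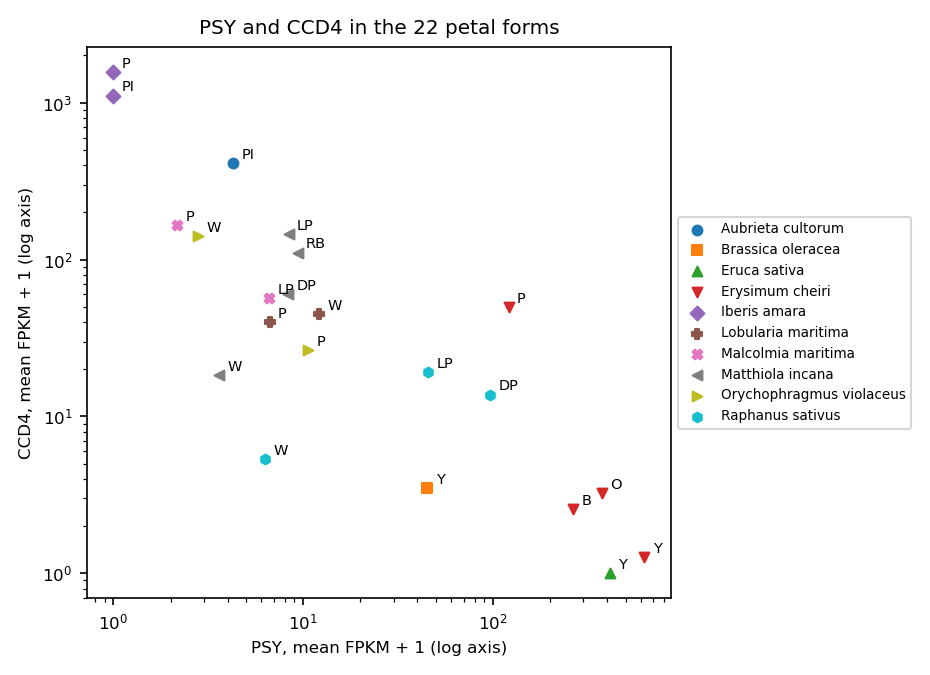
Mean FPKM + 1 of CCD4 against PSY in the 22 petal forms of 10 species. Each point is the mean of the 2 libraries of 1 form with its code beside it, Aubrieta counts 1 library, and a coordinate of 1 means listed at 0.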

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

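The tests of another species in Erysimum P library 2, of plastid loci and of AP1 in Raphanus W, of exchanged labels in Orychophragmus, and the second thinning run there were chosen only after the result was seen. The following genes differed in opposite directions in 2 species that carry the same form codes, with every library of the first form above every library of the second in 1 species and below in the other. The difference was not tested. TT19 in P against W was 1.42 log2 in Lobularia and -3.26 in Orychophragmus, a difference of 4.677, with no call in Lobularia (adjusted p = 0.71). In DP against W, Raphanus and Matthiola differed by 6.612 log2 for F3PRIMEH (6.28 and -0.33), by 13.855 for TT19 (12.25 and -1.60) and by 6.217 for UGT75C1 (4.38 and -1.84). In LP against W, the same species differed by 11.445 log2 for CHS (9.30 and -2.14), by 9.013 for F3H (6.67 and -2.35), by 8.96 for LDOX (8.09 and -0.87) and by 11.761 for TT19 (10.19 and -1.57). In all, 8 of 44 pairs of gene and contrast met this rule, against 2.44 expected by chance if the pairs were independent and held no ties. Genes of 1 pathway and shared W libraries are not independent, and values at 0 are tied. The Raphanus genes named here were listed at 0 in both W libraries, so the size of each Raphanus value is set in part by the 1 added to FPKM and grows with a pseudocount of 0.1. Single Matthiola forms were not tested against W, and a code need not mean the same colour in 2 species.

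Erysimum P library 2 stands apart from the other 7 libraries of its species, with correlations of at most 0.694, and from P library 1 of its own form, which reached 0.868 to 0.891 with the others. Lower depth does not account for it: over the 11923 loci with recovered reads, other libraries thinned to the 163516 reads of P library 2 kept at least 0.809, while P library 2 reached at most 0.553 on these loci. A library of another species stays open, since P library 2 reached 0.775 with Orychophragmus W library 2, and of 78 loci at 0 in the other 7 libraries and at 20 or more in P library 2, 53 were in both Orychophragmus W libraries (67.95%, against 1.38% of all loci at 0 in the 7). A mixture of Erysimum petals with another species also stays open, because 45.5% of 22 loci abundant in the other 7 libraries and listed at 0 in both Orychophragmus W libraries were detected in P library 2 (10 loci, exact 95% interval 24.4% to 67.8%). Form P as such does not set P library 2 apart, since P library 1 is of the same form, and no other biological explanation was tested.

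In Raphanus W the genes CHS, CHIL, F3H, LDOX and TT19 were listed at 0 in both libraries. Lower depth does not account for these zeros: at the depth of the shallower W library, LDOX, TT19 and CHIL would keep at least 58.0 expected reads from a DP library, and CHS and F3H at least 29.0 with an assumed step, against a floor of 3. Plastid loci took 69.2% of W library 1 but 4.08% of W library 2, which lists the same 5 genes at 0. RNA of other floral organs cannot be told apart from a form difference: AP1 in W kept 28.6% of its DP level, AP3 53.5% and PI 13.1%, but sepals share AP1 and stamens share AP3 and PI, and the pollen gene VGD1 was 4170.2 in W against 108 in DP, with AG and SHP1 at 0 in both DP libraries and above 0 in both W libraries. AG in W lay near the worth of a single read. A difference between the forms stays open and untested.

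In Orychophragmus the early flavonoid genes were lower in P than in W. Lower depth of the P libraries was not settled by the planned test. With W thinned to 57161 reads, the median difference over 7 genes was -1.65 log2, against -2.29 without thinning. This median met the bound written before the test, but 100 draws ran from -2.49 to 0. A second run over 11 genes, added after the first result was seen and with an assumed step where none is known, gave -2.37 (draws -3.21 to -2.05, against -2.55 without thinning). No draw of this run came near 0, so thinning did not remove the median difference as far as the assumed steps hold. The run differs from the planned one by genes without a known step, and its median does not speak for each of the 11 genes. Lower depth is thus not settled. Exchanged form labels in all 4 libraries cannot be told apart either, since the highest correlation between libraries of different forms was 0.713 and the lowest within a form 0.768, which is the same for either labelling. Of 5 tapetum and pollen markers 0 were higher in P, with a mean of -3.28 log2 and 0 called. This list had adjusted p = 0.119 by limma camera and 0.102 by limma fry. The camera value was 0.631 with an estimated correlation and 0.0111 with the replicate number as a block. RNA of other floral organs was not tested here and stays open. A difference between the forms stays open and untested.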

How the results depend on the processing

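Voom on whole reads, Erysimum without form P and the list tests without P library 2 were chosen after seeing the data; the cause of a shift was not tested unless stated. Of 189 called results for named genes, 153 held their call and direction with a pseudocount of 0.1, 139 with quantile scaling and 81 of 87 under voom, and none turned its direction; of those not called, 1, 0 and 14 gained a call. Of 48 called list results in 250, 45 held with a pseudocount of 0.1, 43 with quantile scaling, 44 without the filter and 0 with an estimated correlation, while 0, 6, 1 and 0 lists gained a call. Of the called Erysimum list results, 8 held without P library 2, 10 lost the call and 1, the anthocyanin activators in P, turned its direction (adjusted p = 0.971), while 4 gained a call. The median percentile of 8 pigment genes in 22 forms was 86.9 among genes above 0 and 86.8 among genes of at least 1 FPKM. It covers 154 values, since a gene listed at 0 in all libraries of a form has no percentile. Depth limits low genes: loci with a step gave 22221 to 28496 reads per library in Lobularia, where they held 6.78% to 39.1% of the FPKM, and a single read was worth 10.4 FPKM in Raphanus W library 1 and 3.13 FPKM in DP library 2, and 0.375 to 0.561 FPKM in Malcolmia.

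Counts of called genes moved by over 1.5 times as follows. With a pseudocount of 0.1 they became 2 in Malcolmia, 1190 in Orychophragmus, 1481 in Raphanus DP against LP and 787 in LP against W, 15, 184 and 182 in Matthiola DP against LP, DP against RB and LP against RB, and 1 in Erysimum O and 6 in P. Without the filter they became 2 in Malcolmia and 41 in Raphanus LP against W. With quantile scaling they became 2 in Malcolmia, 371, 640 and 29 in Raphanus DP against LP, DP against W and LP against W, 66 in Matthiola DP against RB, and 1 in Erysimum O and 1 in P. Without the variance trend they became 1 in Malcolmia, 0 in Orychophragmus, 462 in Raphanus LP against W, 65 in Matthiola against W, 84 and 266 in Matthiola DP against LP and DP against RB, and 2 in Erysimum B. With only the 2 compared forms in the fit, which leaves fewer samples, they became 520 in Raphanus DP against LP, 0 in LP against W, and 0, 0 and 0 in the 3 Matthiola pairs. Under voom, on fewer loci, they became 60 in Iberis, 22 in Lobularia, 1488 in Malcolmia, 1556 in Orychophragmus, 1902 in Raphanus DP against LP, 174 and 63 in Matthiola DP against LP and LP against RB, and 0, 4 and 0 in Erysimum O, P and Y. With form P left out they became 7 in Erysimum B and 15 in Y.

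Leaving out 1 library at a time, from lowest to highest, gave 0 to 1489 calls in Iberis, 0 to 1732 in Lobularia, 0 to 999 in Malcolmia, 0 to 2277 in Orychophragmus, 1427 to 2538 in Raphanus DP against LP, 1426 to 2650 in DP against W and 0 to 1141 in LP against W. In Matthiola it gave 509 to 1631 against W, 0 to 817 for DP against LP, 0 to 884 for DP against RB and 2 to 559 for LP against RB. In Erysimum it gave 1 to 2165 in B, 0 to 1683 in O, 0 to 5898 in P and 0 to 1819 in Y. The lone library left in a form is assumed to vary like the other groups.

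With the replicate number as a replicate block the counts were 185 in Iberis, 0 in Lobularia, 891 in Malcolmia, 2254 in Orychophragmus, 27, 102 and 5 in Raphanus DP against LP, DP against W and LP against W, 0, 1 and 5 in Matthiola DP against LP, DP against RB and LP against RB, and 1, 1, 0 and 2 in Erysimum B, O, P and Y. Correlations of the within-form differences between forms ran from -0.0464 to 0.0970 except 0.361 for Erysimum O with Y. Outside Erysimum the numbers show no pairing. In Erysimum all 7 heat shock genes were higher in library 2 than in library 1 in O, Y and P and 2 in B, so a shift by replicate number stays open there. Of the called results for named genes with a blocked fit, 69 kept the call and 100 did not, and of the called list results 45 did and 1 did not; 10 such genes and 12 lists gained a call, among them Lobularia heat shock (adjusted p = 0.000929). Matthiola against W has no blocked fit because the W columns carry no number.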

Other observations

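Heat shock genes differed widely between the 2 Erysimum libraries of forms O, Y and P, and little between those of B. Their summed FPKM was 99.1 and 10729 in the 2 libraries of O, 76.2 and 4503 in Y, 315 and 4188 in P, and 14039 and 14270 in B. All 7 were higher in library 2 than in library 1 in O, Y and P, and 2 of 7 in B. Sums of the photosynthesis genes were 2202 and 14201 in O, 1474 and 5423 in Y, 1735 and 22105 in P, and 6490 and 6434 in B. Of the 16 photosynthesis genes 16, 15 and 11 were higher in library 2 in O, Y and P, and 6 in B.

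Aubrieta petals held CCD1 at 1111, the proton pump gene AVP1 at 2428 and RBCS1A at 6835 FPKM. Brassica petals held CCD1 at 942 and 889 and PI at 4164 and 4052. The 2 Eruca libraries differed in LCYE at 2213 and 174, NYC1 at 413 and 1534, SEP3 at 2403 and 937 and RCA at 5464 and 722.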
